A study of Pinellia ternata and uncultivated soil bacterium with 54 samples.

How the data were processed

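Soil bacteria were profiled by amplicon sequencing in 54 libraries, and 11 soil properties were listed for the same 54 samples. Per the labels' protocols, DNA was extracted with a kit for small amounts of sample, blanks gave no 16S amplicon, and libraries followed standard Illumina preparation. The deposited table held raw read counts per operational taxonomic unit (OTU, a cluster of similar sequences) and library, with no normalisation. The clustering program, its identity threshold, the amplified region and any filter were not given in the sources used here. The files used here pair no OTU with a taxon name, so OTUs are given by their IDs.

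Groups came from the soil type in the labels: continuous cropping (24 libraries), rotational cropping (24) and unplanted (6). The soil labels in the authors' table of soil properties were the same as the labels in 54 of 54 libraries. That table also gave the authors' sampling period, which was used as a second grouping added after the data had been seen. It also gave clusters that the authors drew from the same samples, which were not used as groups here. The sample titles carried 4 codes, a G number, a side (L or R), a Y number and a final letter, whose meaning the labels do not give. In the 48 planted libraries each combination of codes occurred once, so the codes were treated only as codes. No pair of libraries within a group had counts within sampling noise: the lowest chi-square per degree of freedom was 4.19 for continuous, 2.61 for rotational and 4.78 for unplanted pairs. Per the deposited notes, 1 pot was drawn at random from each tub every 6 months, and no library is tied to a tub in the labels. Libraries were treated as independent, and p-values measure the spread between these libraries. All sample columns of the table were used.

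Differences between groups were tested on the counts with edgeR (version 4.0.16, R version 4.3.3). TMM factors were estimated on OTUs with at least 10 reads in at least 6 libraries, library sizes were all reads of a library, and quasi-likelihood fits were robust. This left 532 OTUs, which held 45.5% of all reads. The 54 libraries entered 1 fit with the 3 soil groups, and Benjamini-Hochberg adjusted p-values of at most 0.05 were called. The standard error of a log2 fold change was derived from the fold change and its F statistic. TMM factors ran from 0.0804 to 4.31. Title codes were tested in the 48 planted libraries in a fit with all 4 codes. Named OTUs were the called OTUs with the highest mean share in each direction of each soil comparison; 3 per direction had been set and 2 are printed, because no names go with them. Before the data were examined, tests had also been set for genera, phyla, 13 lists of taxa and host or reagent reads. They were not run, because they need taxon names, and the tests set for genera by title code were run on OTUs in their place.

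The number of observed OTUs and the Shannon index (natural logarithm) were computed after rarefying each library to 11229 reads, the smallest total, as the mean of 10 draws. Community composition was compared by PERMANOVA on Bray-Curtis distances of OTU shares. Permutation tests were two-sided, used 100000 permutations, and were replaced by exact enumeration where there were at most 20000 ways to split the samples. The unplanted core was defined as the 736 OTUs detected in all 6 unplanted libraries, so its share in those libraries is high by construction. Distances to the unplanted libraries used the shares of all OTUs, not the core alone. Wilson intervals of 95% and limits for a count of 0 (3 reads) cover counting error only, since amplicon reads are not independent molecules. Soil properties were used in the units that the deposited notes give. Enzyme activities are in µg per g and hour, except urease, whose unit is only partly legible there and is left out.

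Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The scaling and the tool were varied with TMMwsp factors, library totals alone, DESeq2 (version 1.42.0, poscounts size factors) and limma (version 3.58.1) on centred log-ratios with a pseudocount of 0.5. Stricter and looser filters, subsets by title code, title codes as covariates, leaving out OTU280454 and leaving out single libraries were also run.

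The edgeR steps were tested on simulated counts for the 532 OTUs, with 100 OTUs changed 4-fold and 100 changed 16-fold. For continuous against rotational libraries, 63 and 95 of these were called, with 29 of 332 unchanged OTUs also called. For continuous against unplanted libraries the numbers were 30, 70 and 23, and for rotational against unplanted libraries 35, 73 and 14. With the scaling known instead of estimated, the false calls were 4, 8 and 7, and the median log2 change of unchanged OTUs, which was -0.70, -0.80 and -0.51 with estimated factors, was 0.00, 0.16 and 0.11. Estimated scaling gave more false calls than known scaling in these simulations, and the cause was not tested. In 100 simulated sets, the permutation test of means gave 4 results at 0.05 without a shift and 93 with a shift of 2 SD, and PERMANOVA gave 7 without and 100 with a change.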

Results

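Pinellia ternata was grown in pots in a greenhouse, either continuously or in rotation with wheat, to compare the soil microbiomes of both cropping systems. The labels place 24 rhizosphere libraries under continuous cropping, 24 rhizosphere libraries under rotation, and 6 libraries in unplanted bulk soil. Per the deposited notes, rotation followed the continuous phase in time, so cropping system and calendar time were not separated. The table listed 407106 OTUs and 1649409 reads, and 337123 OTUs (82.8%) held a single read. Libraries held 11229 to 67823 reads (median 26402.5). Group means were 32952 ± 18554 reads (SD, n = 24) for continuous, 27378 ± 8614 (n = 24) for rotational and 33579 ± 11340 (n = 6) for unplanted libraries. The 532 OTUs tested one by one held 59.1% of the reads in continuous, 30.5% in rotational and 23.6% in unplanted libraries on average.

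Soil label and title code were not balanced. All 12 libraries with the final title letter e were continuous, and the other continuous libraries were 4 with letter b, 5 with p and 3 with r. Rotational libraries were 8 with letter b, 7 with p and 9 with r (permutation p = 0.00066 for letter by soil label). Comparisons of continuous with rotational soil are therefore given also within letters, and within letter e there was no rotational library to compare.

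A single OTU dominated part of the continuous libraries. OTU280454 held 360473 reads, 21.9% of the whole table, against 17977 for the next most abundant OTU. It exceeded 50% of the reads in 11 libraries, all of them continuous and of title letter e. Its mean share in the 12 letter e libraries was 79.0% ± 25.5 (SD), and its highest share in any other library was 0.674%. In continuous replicate 11 it held 57075 of 61422 reads (92.9%, Wilson 95% interval 92.7 to 93.1%). In continuous replicate 5, the remaining letter e library, it held 29 of 37150 reads (0.0781%, interval 0.0544 to 0.112%). It had no reads in 16 libraries.

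**Figure D1:**
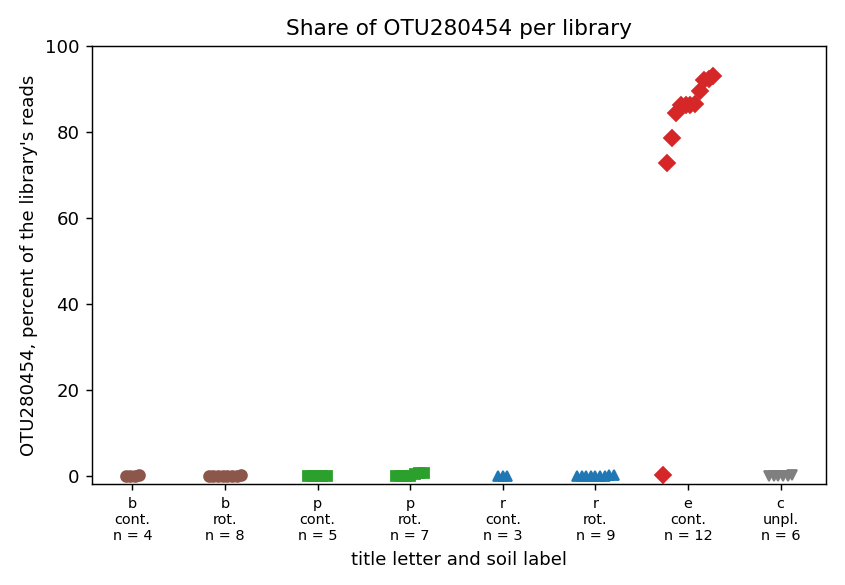
Share of reads taken by OTU280454 (vertical axis, percent) in each library, by title letter and soil label (horizontal axis), with 1 point per library. Of the 12 letter e libraries, 11 lie above 50%, and no other library exceeds 0.674%.

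Continuous cropping soil held fewer OTUs and had a lower Shannon index than rotational cropping soil. At equal depth, continuous libraries held 3419 ± 2607 observed OTUs and rotational libraries 6227 ± 1112 (SD, n = 24 each; difference -2807, permutation test, adjusted p = 0.00012). The Shannon index was 4.51 ± 3.20 in continuous and 7.81 ± 0.609 in rotational libraries (difference -3.30, adjusted p = 0.00012, permutation test). With OTU280454 left out and libraries rarefied to the 903 reads then left in the smallest, the Shannon difference was -0.55 (permutation test, adjusted p = 0.00024). The difference in observed OTUs was then -94.7 (permutation test, adjusted p = 0.00279). Removal of the OTU and the lower depth were not separated in these values. Composition differed too, with the soil label accounting for 9.88% of the variance in Bray-Curtis distance (permutation p = 7e-05). Without the letter e libraries, the difference was -528.9 OTUs (adjusted p = 0.232) and -0.43 in Shannon index (adjusted p = 0.132; 12 continuous and 24 rotational libraries, permutation tests). The label then accounted for 2.84% of the variance (permutation p = 0.428). With labels permuted within title letters, the differences were -415.2 OTUs (adjusted p = 0.235) and -0.36 in Shannon index (adjusted p = 0.143), and p for composition was 0.300. Within single letters, the Shannon index of continuous minus rotational libraries was -0.35 for p (5 and 7 libraries), -0.44 for b (4 and 8) and -0.28 for r (3 and 9). None passed correction over the 12 tests made within letters (exact tests, lowest adjusted p = 0.315).

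Between continuous and rotational soil, 29 of the 532 OTUs were called, 12 higher and 17 lower under continuous cropping (edgeR, Benjamini-Hochberg). The count is weak evidence: 5 of 100 groupings, the real one included, called as many. The simulation of this comparison called 29 of 332 unchanged OTUs. It also held many changed OTUs, whose calls loosen the Benjamini-Hochberg cutoff, so both counts are not directly comparable. A filter of 20 reads in 12 libraries gave 2 of the 94 OTUs then tested, and library totals alone 62 (9 higher, 53 lower). OTU280454 was the most abundant of those that rose, with 39.5% ± 44.0 of the reads in continuous and 0.0834% ± 0.190 in rotational libraries (SD, n = 24 each; log2 fold change 11.75, SE 1.90, adjusted p = 7.83e-06). Its fold change was 8.88 with library totals alone and 6.60 with limma on centred log-ratios (adjusted p = 2.91e-06 and 0.0171). It was detected in 19 of 24 continuous and 16 of 24 rotational libraries. OTU289442 rose as well, from 0.00315% ± 0.0111 in rotational to 0.976% ± 1.18 in continuous libraries (log2 fold change 10.98, SE 1.67, adjusted p = 4.75e-06), and was detected in 11 of 24 continuous and 3 of 24 rotational libraries. Its fold change was 8.06 with library totals alone, 5.40 with limma on centred log-ratios and 12.71 without rotational replicate 12 (adjusted p = 1.52e-06, 0.00405 and 2.03e-07). OTU5200 fell, with 0.923% ± 3.19 in rotational and 0.00211% ± 0.00453 in continuous libraries (log2 fold change -8.31, SE 1.53, adjusted p = 6.29e-05). It was detected in 9 of 24 rotational libraries, and rotational replicate 3 alone held 14.6%; without that library the log2 fold change was -6.64 (adjusted p = 0.000406). With limma on centred log-ratios it was -0.74 (adjusted p = 0.828). OTU17164 fell as well (log2 fold change -4.19, SE 1.26, adjusted p = 0.0306), from 0.158% ± 0.583 in rotational to 0.00983% ± 0.0288 in continuous libraries, but without rotational replicate 6 its change was -2.16 and no longer passed (adjusted p = 0.139). Without continuous replicate 5 it was -5.65 (adjusted p = 0.00150). Its direction turned with DESeq2 (0.66, no adjusted p given) and with limma on centred log-ratios (0.32, adjusted p = 0.913). The median log2 fold change of all 532 OTUs was -0.60, so single changes are relative to that shift. The 12 continuous libraries of letter e differed from the 24 rotational libraries in 342 OTUs (18 higher, 324 lower), whereas the 12 continuous libraries of other letters differed in 1, or in 10 in a fit that kept the unplanted libraries. With title codes as covariates 6 OTUs were called, none of them among these 4. The fold changes of OTU280454 and OTU289442 were then -2.02 and -2.65 (adjusted p = 0.291 and 0.207), and those of OTU5200 and OTU17164 -4.71 and -1.73 (adjusted p = 0.0919 and 0.596).

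Unplanted soil was richer than continuous cropping soil. Unplanted libraries held 7427 ± 238 observed OTUs and had a Shannon index of 8.43 ± 0.0817 (SD, n = 6). Continuous libraries differed from them by -4007 OTUs (adjusted p = 0.00158) and by -3.93 in Shannon index (adjusted p = 0.00766; permutation tests). The difference remained without letter e, at -1729 OTUs (exact test, adjusted p = 0.0206) and -1.06 in Shannon index (exact test, adjusted p = 0.0206). Composition differed with 12.7% of the variance (permutation p = 0.00082), and with 11.8% without letter e (p = 0.00225). The comparison sets rhizosphere under continuous cropping against bulk soil, so planting and sample type were not separated.

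Of the 532 OTUs, 301 differed between continuous and unplanted soil, 171 higher and 130 lower in continuous libraries (edgeR). Which direction held more OTUs depended on the scaling. Library totals alone gave 110 higher and 150 lower, limma on centred log-ratios 151 and 198, and leaving out OTU280454 150 and 155. With TMMwsp factors (174 and 127) and DESeq2 (154 and 92) most were higher. OTU280454 (0.0139% ± 0.0270 in unplanted libraries) rose with a log2 fold change of 15.25 (SE 4.17, adjusted p = 0.00465), or 11.47 with library totals alone and 8.12 with limma on centred log-ratios (adjusted p = 0.00749 and 0.00786). Without unplanted replicate 6 it was 17.65 (adjusted p = 0.00785). OTU296379 held 1.22% ± 2.37 of the reads in continuous and 0.0124% ± 0.0178 in unplanted libraries (log2 fold change 8.06, SE 1.93, adjusted p = 0.00444), and was detected in 24 of 24 and 6 of 6 libraries. Its change was 9.40 without unplanted replicate 6, 6.60 with library totals alone and 6.52 with limma on centred log-ratios (adjusted p = 0.00568, 0.00749 and 4.67e-05). OTU297477 fell from 1.41% ± 0.748 in unplanted to 0.254% ± 0.449 in continuous libraries (log2 fold change -1.92, SE 0.80, adjusted p = 0.0375). OTU303009 fell from 0.510% ± 0.304 to 0.0829% ± 0.122 (log2 fold change -1.94, SE 0.82, adjusted p = 0.0391). Both calls lay near the threshold and were lost without single libraries, though the direction stayed. Without unplanted replicate 1, 2 or 4 the change of OTU297477 was -1.77, -1.54 or -1.96 (adjusted p = 0.0866, 0.138 and 0.0534). Without unplanted replicate 1, 2 or 6 that of OTU303009 was -1.51, -1.79 or -1.89 (adjusted p = 0.150, 0.0853 and 0.0644). Without letter e, 143 OTUs differed, and the fold change of OTU280454 was -0.18 (adjusted p = 0.939). Those of OTU297477 and OTU303009 were then -1.78 and -1.94 (adjusted p = 0.0897 and 0.0634). In a fit of the 2 groups alone they were -1.85 and -1.73 (adjusted p = 0.149 and 0.136). Both falls were called with DESeq2 (-1.90 and -1.91, adjusted p = 0.00905 and 0.00597) and limma on centred log-ratios (-3.16 and -2.76, adjusted p = 0.000190 and 0.000781).

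Rotational cropping soil also differed from unplanted soil, by less than continuous soil did in mean OTU number. Rotational libraries differed from unplanted ones by -1200 OTUs (adjusted p = 0.0170) and by -0.63 in Shannon index (adjusted p = 0.0170, permutation tests). Composition differed with 6.97% of the variance (permutation p = 0.00252). Here too rhizosphere is set against bulk soil, so planting and sample type were not separated. There were 163 OTUs that differed, 144 higher and 19 lower in rotational libraries (edgeR). OTU296379 rose to 1.74% ± 3.16 in rotational libraries (log2 fold change 7.77, SE 1.90, adjusted p = 0.00543) and was detected in 24 of 24. Its change was 9.12 without unplanted replicate 6, 7.11 with library totals alone and 5.89 with limma on centred log-ratios (adjusted p = 0.0102, 0.0177 and 0.000416). OTU5200 rose from 0.00620% ± 0.0134 in unplanted libraries (log2 fold change 7.74, SE 2.76, adjusted p = 0.0271), a change of 6.06 without rotational replicate 3 (adjusted p = 0.0438) and 10.25 without unplanted replicate 2 (adjusted p = 0.0232). That call was lost without unplanted replicate 1, 4, 5 or 6 (log2 fold changes 7.49 to 7.52, adjusted p = 0.0573, 0.0540, 0.0537 and 0.0524), in a fit of the 2 groups alone (8.04, adjusted p = 0.0572) and with limma on centred log-ratios (1.57, adjusted p = 0.278). OTU56804 fell from 0.161% ± 0.0787 in unplanted to 0.0227% ± 0.0268 in rotational libraries (log2 fold change -2.44, SE 0.75, adjusted p = 0.0118). OTU314849 fell from 0.147% ± 0.116 to 0.0226% ± 0.0324 (log2 fold change -2.39, SE 0.81, adjusted p = 0.0192). It did not pass the threshold without unplanted replicate 1 (-1.70, adjusted p = 0.120) or with library totals alone (-2.67, adjusted p = 0.0532). With all OTUs of 10 reads in total, none of the OTUs named here passed, though directions stayed. Adjusted p was then 0.0707 for OTU296379, 0.0715 for OTU5200, 0.0594 for OTU56804 and 0.0638 for OTU314849 (edgeR). Count and direction depended on the scaling: library totals alone gave 100 OTUs (96 higher, 4 lower), and limma on centred log-ratios gave 272, of which most were lower (112 higher, 160 lower).

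The authors' sampling periods ordered the communities in opposite directions under both cropping systems. By these labels, each system was sampled after 0.5, 1 and 1.5 years (M1 to M3 for continuous, R1 to R3 for rotational, 8 libraries each). Whether the labels are independent of the measured communities could not be decided. Under continuous cropping the Shannon index was 7.92 ± 0.394 at M1, 4.63 ± 2.38 at M2 and 0.960 ± 0.250 at M3 (SD, n = 8 each). Under rotation it was 7.07 ± 0.216 at R1, 7.92 ± 0.244 at R2 and 8.44 ± 0.134 at R3, which was close to the 8.43 of unplanted soil (difference 0.00331, exact p = 0.969). The lowest R3 library had 8.13, and the highest M3 library 1.24. Observed OTUs moved alike, from 6537 ± 693 to 768 ± 183 between M1 and M3 and from 5006 ± 597 to 7336 ± 544 between R1 and R3. Of 28 exact tests on both indices, all but the 2 of R3 against unplanted soil passed correction, with adjusted p of at most 0.0111. M1 lay above R1 (difference 0.86, exact p = 0.000311, adjusted p = 0.000518), and M3 below R3 (difference -7.48, exact p = 0.000155, adjusted p = 0.000396).

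**Figure D2:**
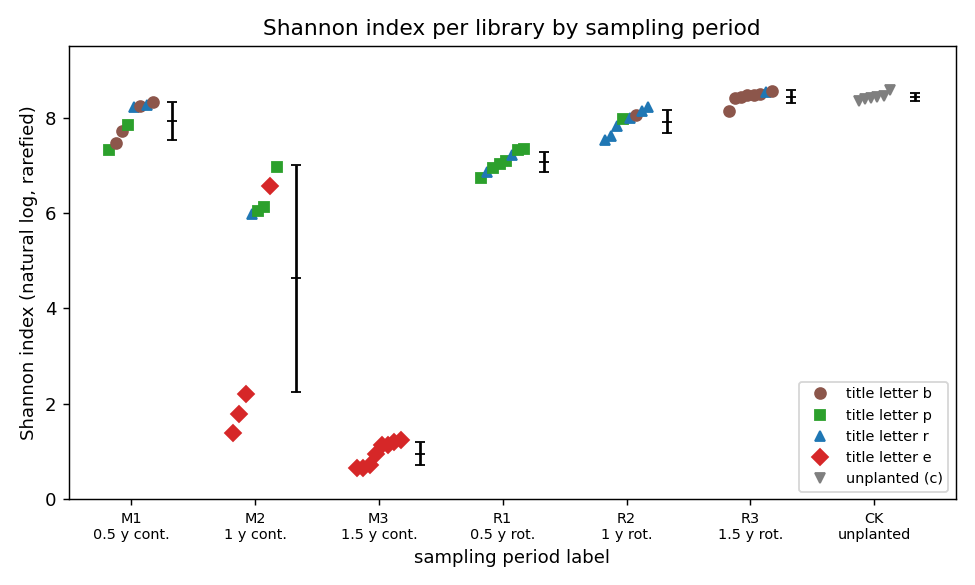
Shannon index of each library (vertical axis, natural logarithm, rarefied) by sampling period (horizontal axis), coloured by title letter, with mean and SD as bars. Means fall from 7.92 at M1 to 0.960 at M3 and increase from 7.07 at R1 to 8.44 at R3; the 8 libraries of M3 are all of letter e.

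The periods differed in title letters as well. M1 was 4 libraries of letter b, 2 of p and 2 of r, M2 was 4 of e, 3 of p and 1 of r, and M3 was 8 of e. R1 was 6 of p and 2 of r, R2 was 6 of r, 1 of p and 1 of b, and R3 was 7 of b and 1 of r. The rise from R1 to R3 thus went with a change of main letter from p to r to b. The mean Shannon index of these letters over planted libraries was 7.06, 7.70 and 8.23. Period accounted for 88.8% of the variance in Shannon index among planted libraries, and the final letter for 89.4%. With period labels permuted within letters p was 1e-05, the smallest that the permutations can give. Within letter e, M3 lay below M2 (0.960 and 2.99 on average, 8 and 4 libraries, exact p = 0.00202, adjusted p = 0.0135). Without continuous replicate 5 the difference fell from 2.03 to 0.84 in size (exact p = 0.00606, adjusted p = 0.0303). Within letter b, R3 and M1 differed by 0.48 (7 and 4 libraries, exact p = 0.0152, adjusted p = 0.0606). The difference was 0.70 between R1 and M2 in letter p (6 and 3 libraries) and 0.84 between R2 and R1 in letter r (6 and 2 libraries; each exact p = 0.0357, adjusted p = 0.0714).

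OTU counts between both cropping systems were lowest at 0.5 years and highest at 1.5 years. M1 and R1 differed in 42 of the 532 OTUs (24 higher and 18 lower at M1), M2 and R2 in 110 (30 and 80) and M3 and R3 in 316 (47 and 269; edgeR). With OTU280454 left out they were 109 (81 and 28), 94 (29 and 65) and 330 (38 and 292), so 0.5 years was then not the lowest. With library totals alone they were 91 (73 and 18), 246 (26 and 220) and 410 (8 and 402). Against unplanted soil, 150 OTUs differed at M1, 353 at M2 and 330 at M3, and 321 at R1, 222 at R2 and 0 at R3. For R3 edgeR gave 61 OTUs at unadjusted p under 0.05, and no OTU was called with library totals alone (56 unadjusted) or without OTU280454 (58 unadjusted). The share of reads in the 736 OTUs of the unplanted core was 27.9% ± 2.05 in unplanted libraries (n = 6), 25.2% ± 2.49 at R3 and 0.707% ± 0.718 at M3 (SD, n = 8 each). Mean Bray-Curtis distance to unplanted libraries was 0.753 ± 0.00960 at R3 and 0.744 ± 0.0149 among unplanted libraries. It was 0.994 ± 0.00453 at M3. Within letter b, R3 lay closer to unplanted soil than M1 (difference -0.0696, 7 and 4 libraries, exact p = 0.00303, adjusted p = 0.0152). Without continuous replicate 23 the difference was -0.0294 (exact p = 0.00833, adjusted p = 0.0417). It was the only such test of nearness to pass within a letter: for the distance adjusted p was 0.976 in letter p, 0.381 in r and 0.0918 in e, and for the core share in letter b 0.0606 (exact tests).

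**Figure D3:**
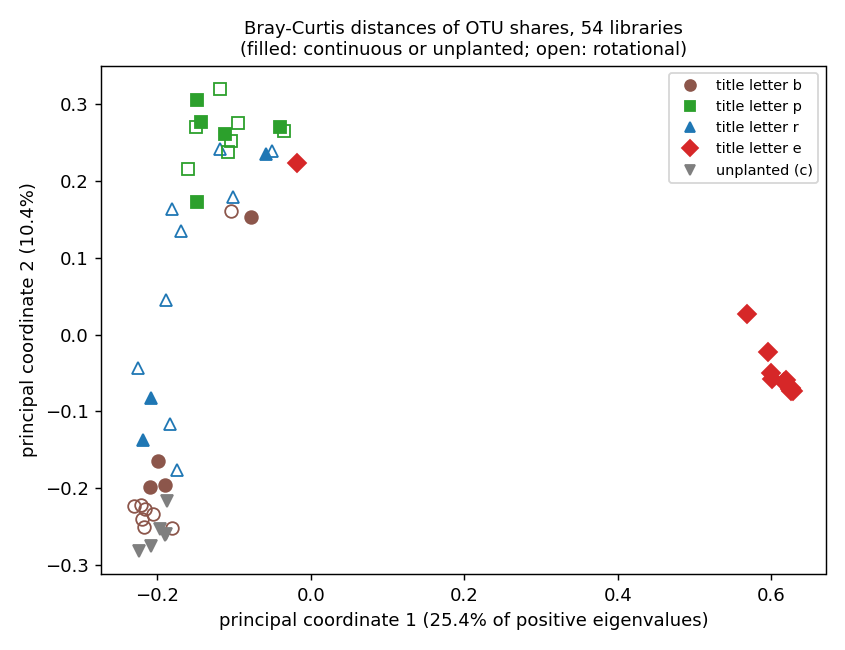
Principal coordinates of Bray-Curtis distances between the 54 libraries (axes carry 25.4% and 10.4% of the positive eigenvalues), coloured by title letter, filled for continuous or unplanted and open for rotational libraries. Of the 12 letter e libraries, 11 lie apart on the horizontal axis, and most letter b libraries lie near the unplanted libraries.

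The final title letter accounted for more of the composition of planted libraries than the other title codes. It accounted for 34.6% of the variance in Bray-Curtis distance (p = 1e-05, the smallest that the permutations can give), against 6.19% for the Y number (p = 0.0719), 2.76% for the side (p = 0.183) and 1.66% for the G number (p = 0.679). In edgeR, 496 of 532 OTUs differed between final letters, 255 by Y number, 108 by side and 7 by G number. Letter b had 436 OTUs that differed from the mean of the other letters (330 higher), letter e 369 (26 higher), letter r 284 (279 higher) and letter p 135 (109 higher). For b, r and p that mean includes letter e, in which 343 OTUs were lower, so their many higher OTUs may reflect letter e. Without letter e, 379 OTUs differed between the final letters, but single letters were not contrasted. The Shannon index was 8.23 ± 0.338 for b, 7.70 ± 0.723 for r, 7.06 ± 0.581 for p and 1.64 ± 1.62 for e (SD, n = 12 each). Adjusted p was 0.0363 for b against r, 0.0363 for r against p and 4e-05 for p against e (permutation tests). Among rotational libraries, which hold no letter e, letter accounted for 15.9% of the variance (p = 0.00011) and period for 19.01% (p = 1e-05). With the other label held fixed, permutation p was 0.332 for letter and 0.00107 for period. Over all planted libraries period accounted for 34.9%, about as much as letter, and with the other label held fixed permutation p was 0.00037 for letter and 0.00011 for period.

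Sucrase, phosphatase and urease were lower in planted than in unplanted soil, while no property passed the test between continuous and rotational soil. The 48 planted libraries carried only 12 distinct sets of soil values, each repeated over 4 libraries of a single title letter. Of these sets, 8 were listed for libraries of both soil labels, and 11 for libraries of more than 1 sampling period (up to 3 periods in 1 set). The 12 sets were therefore compared as single values with the 6 unplanted samples. Whether the sets are independent of each other could not be checked. By the labels, planted libraries are of rhizosphere and unplanted ones of bulk soil, so planting and sample type were not separated. Sucrase was 411 ± 98.1 µg per g and hour in planted sets and 783 ± 272 in unplanted soil (SD; difference -372, exact p = 0.000215, adjusted p = 0.00237 over 11 properties). Phosphatase was 32.6 ± 8.11 and 50.4 ± 13.2 µg per g and hour (difference -17.8, exact p = 0.00189, adjusted p = 0.0104). Urease was 27.9 ± 6.31 and 38.1 ± 9.15 (difference -10.2, exact p = 0.0108, adjusted p = 0.0397). The other 8 properties, pH, nitrogen, potassium and organic matter measures, polyphenol oxidase and protease, had adjusted p from 0.302 to 0.666. With each library counted, 6 of 33 tests passed, the same 3 enzymes for each cropping system against unplanted soil. With each distinct set counted once per label, urease no longer passed for continuous or rotational soil (exact tests, adjusted p = 0.0622 and 0.105). Sharing of 8 sets between both labels means that the table holds little to tell continuous from rotational soil.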

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

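All tests weighed here were chosen only after the results had been seen. Single libraries far from the rest of their group were found in 13 of 61 sets of values. No rate by chance is set beside this count. Several sets were shares at or near 0, where 1 read against 0 is picked by construction.

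Under continuous cropping, replicate 4 had the highest M1 share of OTU280454, 0.0578% against 0.00864% for the next, and replicate 2 the lowest M3 distance to unplanted soil, 0.984 against 0.993. Under rotation, replicate 23 had the highest R2 share of OTU280454, 0.302% against 0.108%. Rotational replicate 21 had the fewest observed OTUs of R3, 6130 against 7183, and its lowest Shannon index, 8.13 against 8.40. Rotational replicate 2, the only R3 library of letter r, lay farthest from unplanted soil, 0.775 against 0.753. In unplanted soil, replicate 3 had the lowest share of core OTUs, 24.03% against 28.1%, and the highest available potassium was 296 mg/kg against 228. Unplanted replicate 6 had the highest shares of OTU280454 (0.0679% against 0.0130%), OTU296379 (0.0470%, 9 reads, against 0.0163%) and OTU289442 (0.00522%, 1 read, against 0). Unplanted replicate 2 had 0.0334% of OTU5200 (15 reads, against 0.00381%), and unplanted replicate 1 had 0.00204% of OTU17164 (1 read, against 0).

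The soil effect differed between G codes for 1 OTU of 532, OTU22869 (log2 difference 12.94, edgeR, adjusted p = 0.0100), and this difference is why it is listed. Without continuous replicate 16, which held 6.46%, its difference was 11.10 (adjusted p = 0.0794) and 0 OTUs were called (37 at unadjusted p under 0.05).

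OTU280454 exceeded 50% of the reads in 11 libraries, all of letter e. Letter e libraries held 9527 more reads on average than other planted libraries (permutation p = 0.0489), but this mean does not decide on low read totals. The 11 libraries included the smallest of all (continuous replicate 3, 11229 reads) and the largest (continuous replicate 8, 67823 reads, 86.5% of them OTU280454). Low totals were argued against only for the large ones. They stay open within M2, where continuous replicate 5 held 37150 reads and replicates 6 and 18, with 15602 and 11932, were dominated by OTU280454. Its share went with sampling period within letter e, at 89.0% in M3 and 58.9% in M2 (exact p = 0.00202, adjusted p = 0.0135; difference 30.03, or 10.4 without continuous replicate 5, adjusted p = 0.0303). Within M2, at one period and cropping system, 4 libraries of letter e held 58.9% and 4 of other letters 0.0114% (exact p = 0.0286, adjusted p = 0.0714), but letter e was singled out from these same libraries, so period, cropping and what the letter codes stay open. OTU280454 carries no name here, and whether it is bacterial or of plant origin was not tested.

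Continuous and rotational libraries differed in 29 OTUs. Uneven title letters may account for many of them: with the 12 continuous libraries of other letters 1 OTU was called, or 10 in a fit that kept the unplanted libraries, and with the 12 of letter e 342. The 342 were counted with TMM factors only, and OTU280454 left few reads for other OTUs in most of these libraries. An effect of cropping itself stays open in letter e, which has no rotational library.

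The Shannon index was ordered by sampling period. Uneven title letters were argued against as the whole cause: in the 36 libraries of letters b, p and r, periods held 86.3% of the variance, more than in any redrawing of the period labels within letters (permutation p = 1.00e-05, the smallest they can give). Library depth was argued against as well, with 88.8% of the variance of the rarefied index between periods and 24.1% of that of total reads. The 8 libraries of M3 were the 8 with the lowest index, and 7 of the next 8 were of M2. All 8 libraries of M2, of M3, of R1 and of R3 each fell in a single cluster of the authors, drawn from the same samples. Of the 12 distinct sets of soil values, 11 were listed for libraries of more than 1 sampling period. Whether period labels were drawn up from the measured communities could not be decided from these counts.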

How the results depend on the processing

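Tests chosen only after the results had been seen were those with library totals, limma, all OTUs of 10 reads, Aitchison, the dominant OTU left out, single codes or libraries, only the 2 groups' libraries, rotational libraries by letter, distinct soil sets, letter as covariate, OTUs and final letter without letter e, Jaccard by title code, OTUs by title code or G code, and all by sampling period; some had been set for genera. The others were chosen before the data were examined. Where a value moved, the cause was not tested.

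Of 83 alternatives for OTU counts, 33 moved the count by over 1.5 times. The 29 OTUs between continuous and rotational soil (12 higher) became 2 with at least 20 reads in 12 libraries, 6 with title codes as covariates, 62 with library totals only (9 higher) and 13 with limma on centred log-ratios. With all OTUs of 10 reads in total, 2676 were called. Without title letter e, in a fit that kept the unplanted libraries, 10 were called, and 5 with title letter as covariate without letter e. Only title letter p gave 0 (edgeR, 50 at unadjusted p under 0.05), only b 2 and only r 1. Only title code G1 gave 8, only G2 12, only side code L 9 and only R 7.

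The 301 OTUs between continuous and unplanted soil became 60 with at least 20 reads in 12 libraries, 3872 with all OTUs of 10 reads in total and 143 without title letter e. Leaving out single unplanted libraries gave 236 to 283. The 163 between rotational and unplanted soil became 26 with 20 reads in 12 libraries, 100 with library totals only, 298 with all OTUs of 10 reads in total and 272 with limma on centred log-ratios. Leaving out single unplanted libraries gave 126 to 163.

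By title code, the G number gave 15 OTUs with each code alone, 2 with 20 reads in 12 libraries and 4 without title letter e, against 7. The side gave 16 with 20 reads in 12 libraries, against 108. The Y number gave 140 with each code alone and 43 with 20 reads in 12 libraries, against 255. The final letter gave 93 with 20 reads in 12 libraries, against 496. The difference of soil effect between G codes gave 2 with library totals only and 0 without the library richest in the OTU named, against 1. M1 and R1 differed in 91 OTUs with library totals only and 109 with the dominant OTU left out, against 42. M2 and R2 differed in 246 with library totals only, against 110.

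Single OTUs reversed in 15 of 202 alternatives. OTU280454, 11.75 between continuous and rotational soil, was -2.02 with title codes as covariates, -2.54 without title letter e, -4.18 in only title letter p, -3.71 in only title letter r and -1.94 with title letter as covariate without letter e. Against unplanted soil it was -0.18 without title letter e. OTU289442, 10.98, was -2.65 with title codes as covariates, -2.91 without title letter e, -4.61 in only title letter p and -2.67 with title letter as covariate without letter e. OTU5200, -8.31, was 1.66 in only title letter b. OTU17164, -4.19, was 0.66 with DESeq2, 0.32 with limma on centred log-ratios, 1.53 in only title letter b and 0.48 in only title code G2. In 45 more the direction stayed but the call was lost.

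Diversity tests lost their call in 4 of 30 alternatives, all between continuous and rotational soil. Observed OTUs differed by -528.9 without title letter e and by -415.2 with labels permuted within title letter. The Shannon difference was -0.43 without title letter e and -0.36 with labels permuted within title letter. Others kept their call but shrank. With the dominant OTU left out, the Shannon difference was -0.55 between continuous and rotational soil (-3.30 before) and -0.90 between continuous and unplanted soil (-3.93 before). Without title letter e, continuous and unplanted soil differed by -1729 OTUs (-4007 before) and -1.06 in Shannon index.

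Community composition gained or lost a call in 10 of 47 alternatives. Between continuous and rotational soil, 9.88% of the variance had permutation p = 0.300 with labels permuted within title letter, and 2.84% remained without title letter e (p = 0.428). The call was kept with smaller shares of the variance for Jaccard (2.86%), Hellinger (4.63%), Aitchison (4.41%) and the dominant OTU left out (5.43%). In rotational libraries, the 15.9% of title letter had p = 0.332 with labels permuted within sampling period. The side, 2.76% before, accounted for 2.37% with Jaccard (p = 0.0353), 4.60% with Aitchison (p = 0.0298) and 3.11% with the dominant OTU left out (p = 0.0424). The Y number, 6.19% before, accounted for 4.98% with Jaccard (p = 0.00107), 5.83% with Hellinger (p = 0.00643), 11.1% with Aitchison (p = 0.00120) and 6.998% with the dominant OTU left out (p = 0.00212).

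Of soil properties, urease lost its call, at a similar difference. With distinct sets counted once, it differed from unplanted soil by -10.3 (-9.95 before) for continuous and -9.90 (-10.5 before) for rotational soil (exact tests, adjusted p = 0.0622 and 0.105).

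Alternatives for genera (with their distances), phyla, lists of taxa, host or reagent reads and organelle removal were not run, because they need taxon names. Nor was a filter on low depth.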

Other observations

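All tests reported here were chosen only after the results had been seen. Single OTUs were enriched or depleted in title letters among planted libraries. For letters b, p and r, the other letters include letter e. OTU7933 held 2.04% ± 3.33 of the reads in letter p and 0.0897% ± 0.328 in the other letters (SD, n = 12 and 36; log2 fold change 5.46, SE 0.64, edgeR adjusted p = 1.80e-09). Without continuous replicate 20, which held 12.02%, letter p had 1.13% ± 1.15 and the fold change was 4.53 (adjusted p = 8.33e-08). OTU4075 held 1.22% ± 2.65 in letter r and 0.0450% ± 0.0651 elsewhere (log2 fold change 5.57, SE 0.79, adjusted p = 1.19e-06). Without continuous replicate 19, which held 9.12%, letter r had 0.502% ± 0.954 and the fold change was 3.35 (adjusted p = 0.000356). OTU303454 held 0.0610% ± 0.0371 in letter b and 0.0113% ± 0.0253 elsewhere (log2 fold change 3.68, SE 0.51, adjusted p = 2.46e-07), or 2.74 without continuous replicate 23 (adjusted p = 3.92e-05). OTU296746 fell in letter e to 0.000124% from 0.287% ± 0.269 (log2 fold change -6.94, adjusted p = 1.62e-06), or -8.79 without continuous replicate 14, the only letter e library with a read of it (adjusted p = 3.63e-06).

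Labels were redrawn so that 100 groupings, the real one among them, could be compared by their count of called OTUs. For continuous against rotational soil, 5 of 100 groupings called at least the real 29 (highest other 64), so chance was not excluded. For continuous against unplanted soil it was 1 of 100 (real 301, highest other 121), and for rotational against unplanted soil 1 of 100 (real 163, highest other 152). That is the lowest share that 100 groupings can give, and it is not corrected over the comparisons. It argues against chance for continuous soil. For rotational soil it is weaker evidence, since a redrawn grouping came close to the real count. By code it was 3 of 100 for the G number (7; 67), and 1 of 100 each for the side (108; 38), the Y number (255; 12) and the final letter (496; 127). For the side, the Y number and the final letter the real count was the highest of the 100. This argues against chance at 1 in 20, before correction over the comparisons. The G number is weak evidence, because its share is not corrected either and single redrawn G numbers called several times the real count. That may reflect structure among the samples, which was not tested. The real codes are balanced over each other and the redrawn ones are not, so the groupings also differ in that. The difference of soil effect between G codes reached its real 1 in 64 of 100 (highest other 92), so chance was not excluded. Each title letter was reached in 1 of 100: b (436; 127), e (369; 81), p (135; 52) and r (284; 227).

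Between periods, M1 against R1 was reached in 4 of 100 (42; highest other 56), M2 against R2 in 2 of 100 (110; 160) and M3 against R3 in 1 of 100 (316; 66). For M3 against R3 the real count was the highest of the 100, which argues against chance at 1 in 20, before correction over the comparisons. The counts for M1 and M2 are weaker evidence, since single redrawn groupings lay above them and the shares are not corrected over the comparisons. Against unplanted soil it was 1 of 100 each for M1 (150; 102), M2 (353; 180), M3 (330; 80), R1 (321; 51) and R2 (222; 53). For R3, with 0 called, all 100 reached it by construction (highest other 12), so this count says nothing about chance.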
